A study of Mus musculus with 4 samples.

How the data were processed

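RNA sequencing was used to compare Mmp3-positive with Mmp3-negative cells of the stromal vascular fraction, the non-adipocyte cells released from adipose tissue, from subcutaneous fat of wild-type C57BL/6 mice. There were 2 libraries per group, 4 in all, numbered 1 and 2 in each group in the labels. The labels did not say that libraries came from separate animals, so p-values measured only the spread between these samples, which may be technical. Per the labels' protocols, total RNA was extracted with a kit made for formalin-fixed, paraffin-embedded material, ribosomal RNA was depleted and libraries were strand-specific. How the cells were separated, beyond a reagent code, was not given in the sources used here.

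Per the submitters' processing notes, reads were quantified with kallisto 0.45.0 and the genome build was GRCm38. The deposited tables held an estimated count, a TPM value and an effective length for each of 115270 transcripts per library, per the file headers. The transcript set, the strand setting and any read trimming were not given in the sources used here. kallisto shares reads among similar transcripts, so the values of near-identical genes are uncertain, and fragments from transcripts outside the index can be assigned to listed ones.

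Transcripts were matched to GENCODE M21 genes on GRCm38 by identifier without version. There were 113580 matches in 35580 genes, of which 22013 were protein-coding, and 1690 transcripts matched no gene and were left out. They held 2.08% and 0.729% of the estimated counts in Mmp3-negative replicates 1 and 2, and 0.809% and 0.995% in Mmp3-positive replicates 1 and 2. Estimated counts were summed per gene and rounded to whole numbers. Totals before matching were 18629081 and 17693755 in the Mmp3-negative libraries and 19026779 and 20286221 in the Mmp3-positive libraries.

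Genes were kept by filterByExpr with a minimum count of 10, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3) without a covariate, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. The fit left 2 residual degrees of freedom. Standard errors were the log2 fold change over the square root of the F statistic. Levels are TMM-normalised CPM, counts scaled to a common library size, as mean ± SD with n = 2.

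There were 32 gene lists, and 24 of them had the 5 tested members needed for camera (limma 3.58.1) with a preset correlation of 0.01. An estimated correlation and fry were alternatives. Altogether 8 list symbols were not among the genes. Named genes were Mmp3 and, in each direction, up to 12 genes past the threshold with an average logCPM of at least 3, the same sign in both numbered sets and no predicted name. Where fewer than 10 passed, the 10 with the smallest p were given as values only. For each list, up to 4 members past the threshold, or otherwise the 2 most abundant, were taken. Not every gene taken for a list is printed, and 1 of them is not reported here. The groups, the tests, the lists, this rule and the alternatives were set before the data were examined, except for voom with a quality weight per group and a floor of average logCPM 5. Other genes named below were chosen after their values were seen: Pdgfra, Pdgfrb, Agt, Cd36, Mmp19, Adamts9, Adamts4, Timp1, Ccl7, Ccl11, Jun, Jund, Fosb, Atf3, Des, Acta2, Lmod1, H2-Eb1, Kdr, Lama5, Dnajb1, Nkd1, Laptm5, Meox2, Pnpla2, Ccnb1ip1, Gm12895 and Gm12896.

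The alternatives were DESeq2 size factors, no count filter, the DESeq2 1.42.0 Wald test, the set number as a replicate block, leaving out each library in turn, an offset for average transcript length, protein-coding genes only, and limma on log2(TPM + 1) with a pseudocount of 1. The deposited TPM values were used there and as weights for the transcript lengths of the length offset, so these alternatives share an input. Where a library was left out, the remaining library of its group was assumed to vary like the other group. The filter then kept more genes (15980 to 16358, against 14185 with all 4 libraries). List medians of those fits can therefore cover other members, and the median with all 4 libraries can lie outside their range.

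The tests were tried on simulated counts for this comparison, with 100 genes changed by each fold size. With the dispersion of these libraries, 36.0% of the 4-fold and 62.0% of the 16-fold changes were recovered, with 9 calls among unchanged genes. With a dispersion 10 times lower the shares were 90.0% and 99.0%, with 13 such calls. A planted list lower by 2-fold was recovered, and 0 of 20 random lists were called at either dispersion. Simulated genes varied independently, with the same dispersion in both groups, so list calls were not tried with correlated members. Estimated correlations of the tested lists reached 0.524, in fibrillar collagens and matrix. Python 3.11.15 with pandas 2.3.3 and matplotlib 3.10.9 was used for sums and plots.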

Results

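Gene expression was measured by RNA sequencing in Mmp3-positive and Mmp3-negative cells of the stromal vascular fraction of mouse subcutaneous adipose tissue, with 2 libraries per group. This fraction holds fibroblast-like stromal cells and adipocyte progenitors together with mural, endothelial and immune cells. The libraries held between 17693755 and 20286221 estimated counts. At least 10 counts were found for 12953 and 12697 genes in the Mmp3-negative libraries and for 14382 and 13720 genes in the Mmp3-positive libraries. The labels named a single comparison, which asked how the expression of the Mmp3-positive cells differed from that of the Mmp3-negative cells.

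**Figure D1:**
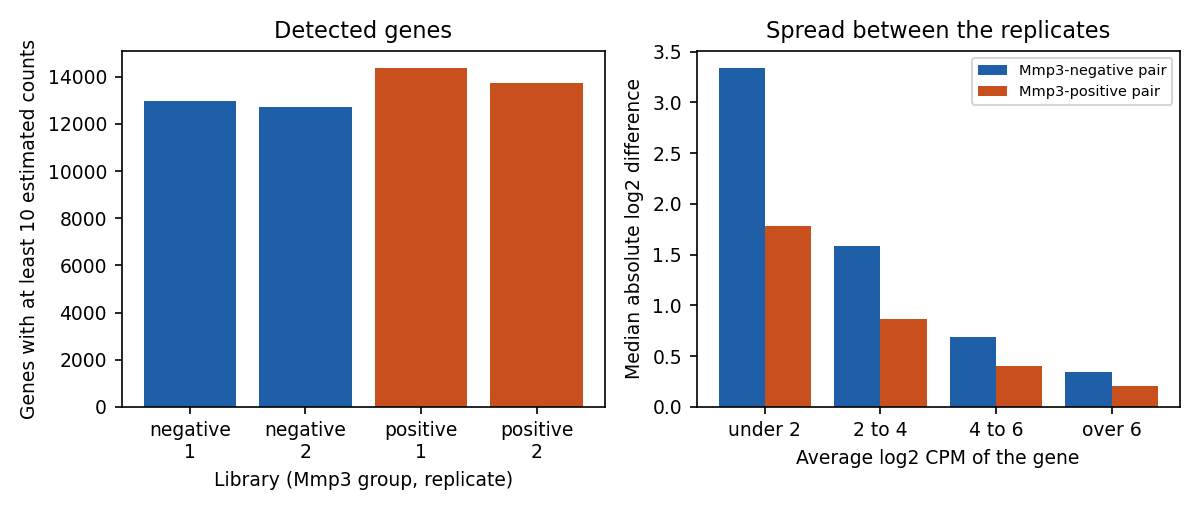
Left, the number of genes with at least 10 estimated counts in each library, between 12697 and 14382. Right, the median absolute log2 difference between the replicates of each group by average log2 CPM of the gene, which was larger in the Mmp3-negative pair in every class (3.34 against 1.78 under an average of 2).

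Mmp3, which encodes the secreted matrix metalloproteinase stromelysin-1, was 32.0-fold higher in Mmp3-positive cells. Its level was 118 ± 17.2 CPM in the Mmp3-negative and 3785 ± 532 CPM in the Mmp3-positive libraries (SD, n = 2). The standard error of the log2 fold change was 0.21 (edgeR adjusted p = 0.00793). The gene (ENSMUSG00000043613) lies on chromosome 9 of GRCm38 from 7445822 to 7455975. Mmp3 defined the groups, so this difference checks the labels. With limma on log2(TPM + 1) the log2 fold change was 5.27 and the adjusted p was 0.545.

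Of 14185 genes tested, 1 was higher in Mmp3-positive cells, Mmp3, and 2 were lower, Hspa1a and Hspa1b. Both encode the inducible heat shock protein Hsp70. Hspa1a fell from 2534 ± 186 to 381 ± 37.4 CPM (log2 fold change -2.73, standard error 0.16, edgeR adjusted p = 0.0250), and Hspa1b from 2459 ± 278 to 457 ± 3.44 CPM (-2.43, standard error 0.15, edgeR adjusted p = 0.0273). The pair is nearly identical and adjacent on chromosome 17, so how reads were divided between the genes is uncertain. Summed, the pair stood at 4992 ± 464 CPM in Mmp3-negative and 839 ± 34.0 CPM in Mmp3-positive libraries, a ratio of 5.95. Both calls were lost without Mmp3-positive replicate 1 or replicate 2. They were also lost with the length offset (adjusted p = 0.108 for Hspa1a and 0.125 for Hspa1b) and with limma on log2(TPM + 1) (0.545 for both). In these fits the log2 fold change ran from -2.84 to -2.43 for Hspa1a and from -2.435 to -2.12 for Hspa1b. Without Mmp3-negative replicate 1, 234 genes were higher and 98 lower, and without its replicate 2, 237 and 116. With all 4 libraries, DESeq2 called 447 higher and 532 lower.

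**Figure D2:**
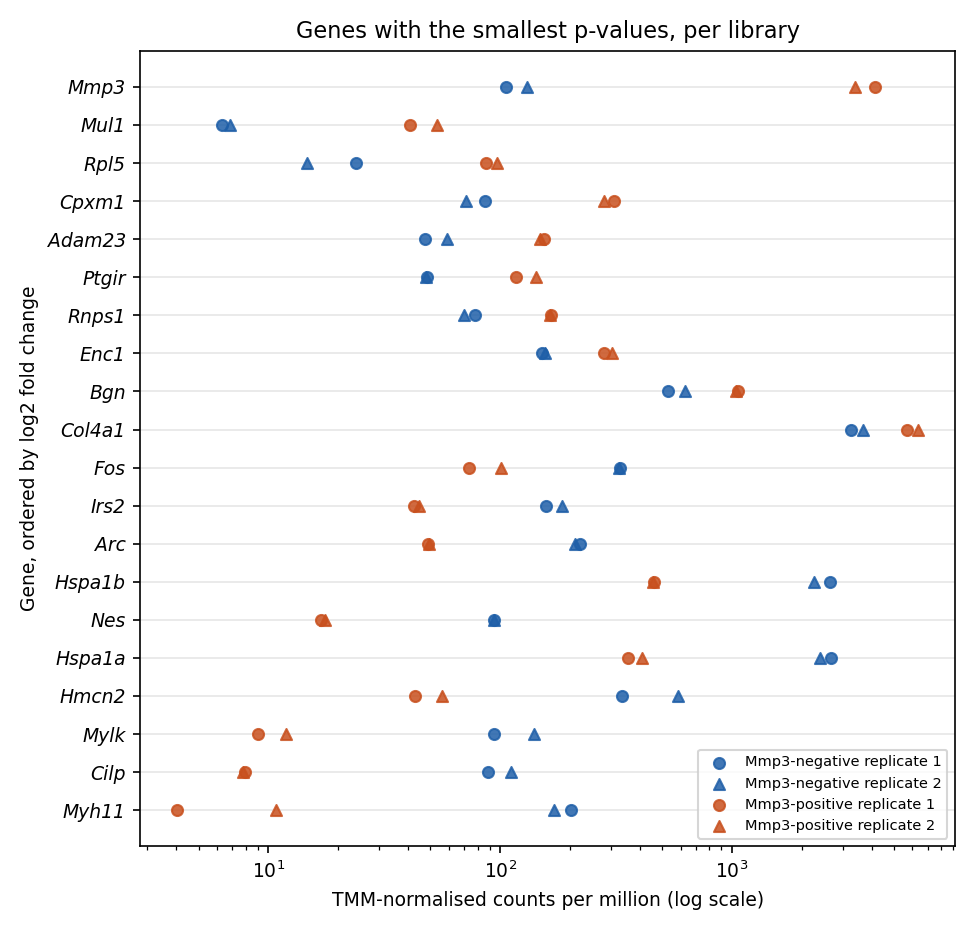
TMM-normalised CPM, on a log axis, of Mmp3 and the other genes with the smallest p in each direction, ordered by log2 fold change. Each point is a library, coloured by group, and the Mmp3 points of the Mmp3-positive libraries (mean 3785 CPM) lie to the right of those of the Mmp3-negative libraries (mean 118 CPM).

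The other genes with the smallest p did not pass the threshold (edgeR adjusted p between 0.178 and 0.480), and their values follow. On the higher side, Cpxm1, a carboxypeptidase-like secreted protein, had a log2 fold change of 1.91 and a level of 296 ± 21.7 CPM against 78.5 ± 10.2 CPM. The log2 fold change was 1.51 for Adam23, a membrane protein of the disintegrin and metalloproteinase family, and 1.43 for Ptgir, the prostacyclin receptor. It was 0.79 for Col4a1, a basement membrane collagen, and 0.86 for Bgn, the proteoglycan biglycan. It was 2.25 for Rpl5, a ribosomal protein gene whose reads can be shared with pseudogenes, 1.16 for Rnps1, a splicing regulator, 0.93 for Enc1, an actin-binding protein, and 2.84 for Mul1, a mitochondrial ubiquitin ligase. On the lower side, the matrix protein genes Cilp and Hmcn2 had log2 fold changes of -3.67 and -3.22. The smooth muscle genes Myh11, a myosin heavy chain, and Mylk, its light chain kinase, had -4.65 and -3.48. The immediate early genes Arc and Fos had -2.13 and -1.91, Irs2, an insulin receptor substrate, had -1.98, and Nes, the intermediate filament nestin, had -2.45.

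Stromal fibroblast genes were higher as a group in Mmp3-positive cells, with a median log2 fold change of 0.48 over 18 members (camera adjusted p = 9.42e-05, adjusted p = 0.389 with an estimated correlation). No member passed among all genes (0 of 18), and 3 were higher when adjusted over the list alone. Pdgfra and Pdgfrb, receptors for platelet-derived growth factor, had log2 fold changes of 0.75 and 0.76, and Gsn, the actin-severing protein gelsolin, stood at 6651 ± 1050 CPM against 10910 ± 562 CPM. Col1a1, the main fibrillar collagen, stood at 7558 ± 2488 CPM against 8125 ± 2329 CPM. The mural, endothelial, macrophage and dendritic marker lists had medians between -2.90 and -1.80 in the same comparison. The stromal fibroblast call was lost with fry (adjusted p = 0.170) and with limma on log2(TPM + 1) (0.0562). The committed preadipocyte list had a median of 0.43 over 17 members (camera adjusted p = 0.038, adjusted p = 0.389 with an estimated correlation), with 0 members past the threshold among all genes and 3 higher when adjusted over the list alone. Its members went both ways, from Agt, the angiotensinogen gene, at 0 counts in both Mmp3-negative libraries and 14.9 ± 4.34 CPM in the Mmp3-positive ones, to the fatty acid transporter Cd36 at -2.30. Its call was lost on leaving out any library, where the median ran from 0.48 to 0.64. It was also lost with no count filter (camera adjusted p = 0.0532), with the length offset (0.0600), with limma on log2(TPM + 1) (0.197) and above an average logCPM of 5 (0.0991).

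Ribosomal protein genes had a median log2 fold change of 0.24 over 25 members (camera adjusted p = 0.00161, adjusted p = 0.389 with an estimated correlation). Of these, 0 passed among all genes and 1 was higher when adjusted over the list alone. Rpsa stood at 1036 ± 236 CPM against 1289 ± 116 CPM and Rpl3 at 715 ± 95.5 CPM against 848 ± 43.3 CPM. Without Mmp3-negative replicate 1 the median was 0.12 and the call was lost (adjusted p = 0.0895), as it was with fry (0.104) and with limma on log2(TPM + 1) (0.0708). Without Mmp3-negative replicate 2 the median was 0.37. Between replicates these genes differed by a median absolute log2 difference of 0.283 in the Mmp3-negative and 0.138 in the Mmp3-positive pair.

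Immediate early and heat shock genes, which are induced within minutes by stress or stimulation, were lower as a group in Mmp3-positive cells. The median log2 fold change was -0.89 over 22 members (camera adjusted p = 6.47e-19, adjusted p = 0.192 with an estimated correlation). Among all genes 2 members were lower, Hspa1a and Hspa1b, and 12 were lower when adjusted over the list alone. Members that did not pass among all genes included the AP-1 transcription factor genes Fosb (-3.12), Jun (-1.39) and Jund (-1.42), the stress-induced factor Atf3 (-2.30) and the co-chaperone Dnajb1 (-1.52).

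The marker lists of mural, endothelial, macrophage and dendritic cells were lower as groups in Mmp3-positive cells, by the tests that follow. Pericyte and smooth muscle genes had a median log2 fold change of -2.82 over 14 members (camera adjusted p = 1.18e-14, adjusted p = 0.192 with an estimated correlation). Among all genes 0 passed, and 7 were lower when adjusted over the list alone. Notch3, a receptor of mural cells, stood at 212 ± 14.7 CPM against 23.1 ± 13.2 CPM, and Myh11 at 187 ± 22.5 CPM against 7.45 ± 4.80 CPM. Desmin (Des) stood at 62.3 ± 9.36 CPM against 3.14 ± 1.61 CPM and smooth muscle actin (Acta2) at 70.6 ± 22.3 CPM against 13.3 ± 10.2 CPM. Lmod1, a smooth muscle actin nucleator, did not pass among all genes (edgeR adjusted p = 0.480) and had 0 counts in both Mmp3-positive libraries, at least 129-fold lower against a floor of 3 counts per library.

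Endothelial genes had a median of -1.94 over 12 members (camera adjusted p = 9.42e-05, adjusted p = 0.389 with an estimated correlation), with 0 past the threshold among all genes or when adjusted over the list alone. Eng and Pecam1, endothelial surface proteins, had log2 fold changes of -0.24 and -0.76, and Kdr, the receptor for vascular endothelial growth factor, had -1.67. The endothelial call was lost without Mmp3-negative replicate 1 (adjusted p = 0.141) and with fry (0.218). Macrophage and monocyte genes had a median of -2.90 over 12 members (camera adjusted p = 6.51e-07, adjusted p = 0.239 with an estimated correlation), with 0 past the threshold among all genes or adjusted over the list alone. Cd68, a lysosomal protein of macrophages, stood at 36.3 ± 3.48 CPM against 11.7 ± 7.08 CPM, and C1qb, a complement component, at 44.6 ± 48.1 CPM against 8.05 ± 11.3 CPM. The macrophage call was lost with fry (adjusted p = 0.104). Dendritic and antigen presentation genes had a median of -1.80 over 7 members (camera adjusted p = 6.85e-05, adjusted p = 0.274 with an estimated correlation), with 0 past the threshold among all genes and 1 lower when adjusted over the list alone. Cd74, the invariant chain, stood at 52.9 ± 46.3 CPM against 1.79 ± 2.46 CPM. Zbtb46, the other member taken by the rule, stood at 19.0 ± 5.88 CPM against 11.2 ± 9.18 CPM (log2 fold change -0.77). H2-Eb1, an MHC class II gene, had 0 counts in both Mmp3-positive libraries, at least 179-fold lower, and did not pass (edgeR adjusted p = 0.480). With a library left out in turn the dendritic median ran from -8.30, without Mmp3-positive replicate 1, to -2.54, without Mmp3-negative replicate 1. In Mmp3-positive replicate 2 Cd74 stood at 0.0509 CPM and H2-Eb1 at 0 counts, so the size of folds against that library alone is uncertain. The dendritic call was lost with fry (adjusted p = 0.0982).

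Schwann cell genes had a median of -0.74 over 8 members (camera adjusted p = 0.037, adjusted p = 0.389 with an estimated correlation) and WNT signalling genes a median of -0.31 over 17 members (camera adjusted p = 0.038, adjusted p = 0.389 with an estimated correlation). In each, 0 members passed among all genes or when adjusted over the list alone. The myelin gene Pmp22 stood at 51.4 ± 18.8 CPM against 30.8 ± 22.6 CPM. The secreted WNT inhibitor Sfrp2 stood at 112 ± 18.3 CPM against 103 ± 37.1 CPM, and Nkd1, an intracellular WNT inhibitor, had a log2 fold change of -2.82. With each library left out in turn the Schwann cell median ran from -1.68 to -1.15 and the WNT median was -0.59 or lower. The Schwann cell call was lost without Mmp3-positive replicate 1 (adjusted p = 0.164), and the WNT call without that library or either Mmp3-negative library (adjusted p between 0.0790 and 0.144), and both were lost with the length offset (0.0879 and 0.0600), with limma on log2(TPM + 1) (0.0955 and 0.0597) and with fry (0.0982 and 0.104). The WNT call was also lost above an average logCPM of 5 (adjusted p = 0.943).

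**Figure D3:**
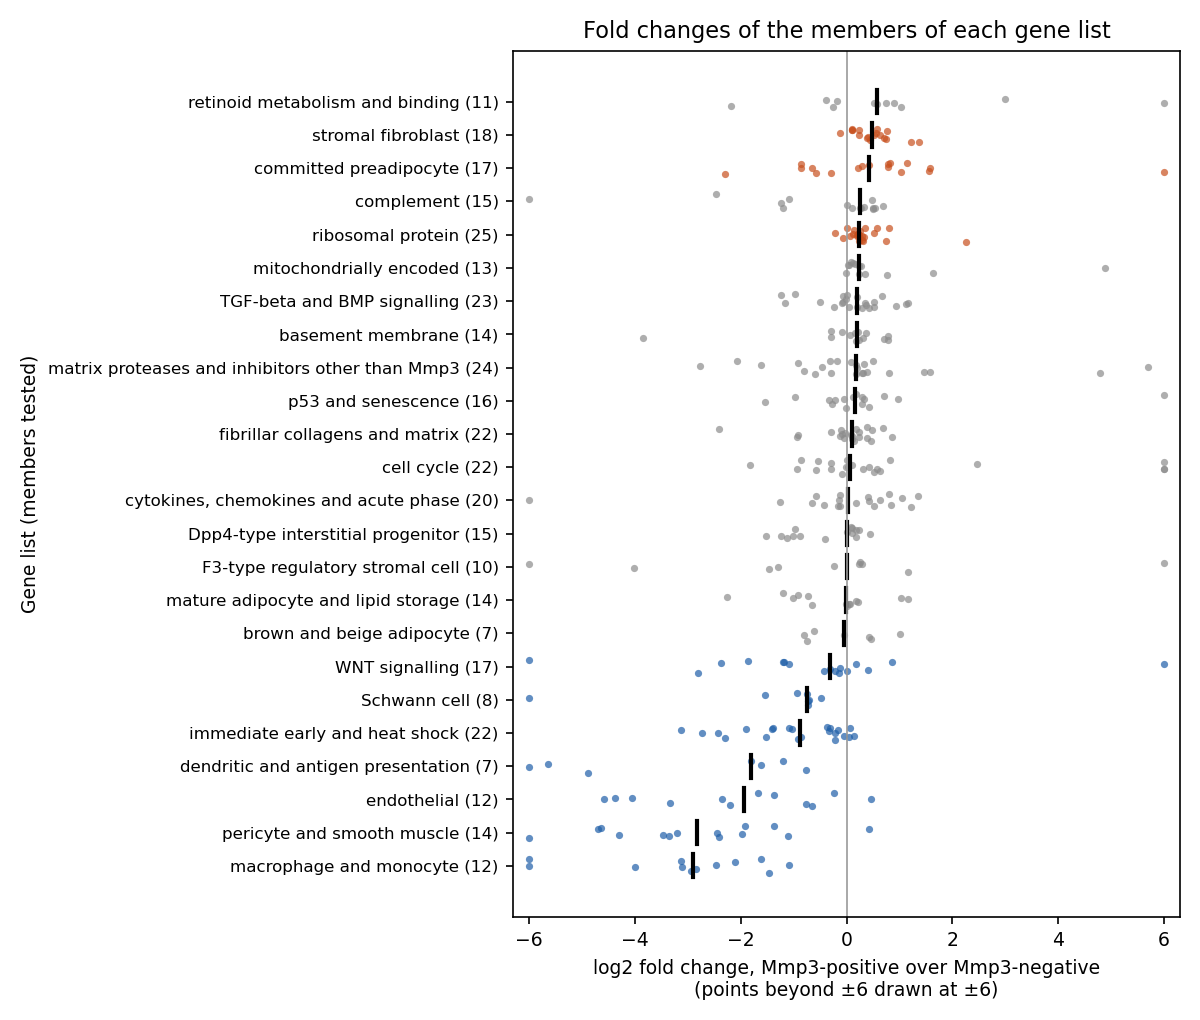
Log2 fold change, Mmp3-positive over Mmp3-negative, of the tested members of each of the 24 lists tested, with a black bar at the median and points beyond the axis drawn at its ends. Coloured lists passed the camera test (orange higher, blue lower), and the lowest medians were those of macrophage and monocyte (-2.90) and pericyte and smooth muscle (-2.82) genes.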

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

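Transcripts that matched no gene were outside the comparison and held 2.08% of the estimated counts in Mmp3-negative replicate 1. That is above the 1.6e-05% that 3 counts, the limit set by a count of 0, would make of that library. The shares of the other libraries were far above that limit too, so it does not single out this library. The share was 0.729% in Mmp3-negative replicate 2 and 0.809% and 0.995% in the Mmp3-positive libraries. A single unmatched transcript held 1.61% in Mmp3-negative replicate 1 and 0.153% in replicate 2. Its estimates equalled those of the processed pseudogenes Gm12895 and Gm12896, which were matched to genes, in all 4 libraries.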

How the results depend on the processing

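The voom fit with a weight per group and the floor of average logCPM 5 were chosen after seeing the data. The Mmp3 log2 fold change stayed between 4.85 and 5.27 under every alternative and past the threshold in all but limma on log2(TPM + 1) (5.27, adjusted p = 0.545), which moved the median of all genes from 0.02 to 0.29. DESeq2 size factors and protein-coding genes alone gave the same counts of genes and lists. Apart from these, the cause of each difference below was not tested. Leaving out a library left fewer samples but more tested genes (15980 to 16358, against 14185), so list medians can cover other members. The logCPM floor left fewer genes (5310).

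Genes higher and lower numbered 4 and 23 with no count filter, 447 and 532 with the DESeq2 Wald test, 1 and 0 with the length offset (1183 genes at unadjusted p under 0.05), 0 and 0 with limma on log2(TPM + 1) (1064 genes), 11 and 18 with voom, and 2 and 21 above the logCPM floor. Leaving out a library gave 1 to 237 higher and 1 to 116 lower genes, with the large counts on leaving out either Mmp3-negative library. The spread was then taken from the Mmp3-positive pair, whose median absolute log2 difference was 0.501 against 0.795 in the Mmp3-negative pair. Of the 3 called genes, 1 was also called without either Mmp3-positive library or with the length offset, 0 with limma on log2(TPM + 1), and all 3 without either Mmp3-negative library. With the set number as a replicate block, 1 gene was higher and 4 were lower, among them all 3 called genes; the correlation of same-numbered deviations was 0.026, with 2 pairs.

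Lists higher and lower numbered 0 and 0 with an estimated correlation (lowest adjusted p 0.192), 1 and 2 with fry, 0 and 5 with limma on log2(TPM + 1), 6 and 7 with voom, which added mitochondrially encoded (adjusted p = 0.00572), basement membrane (0.00197) and complement genes (0.0499), 3 and 2 above the logCPM floor, where complement passed (adjusted p = 0.0352), committed preadipocyte (0.0991) and WNT genes (0.943) did not, and 4 of the lists called lower had too few members, 3 and 6 with the block, which ended the committed preadipocyte and Schwann cell calls (adjusted p = 0.0578 each) and called mitochondrially encoded genes higher (0.0299), and 1 to 2 and 5 to 7 without a library in turn.

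Results that turned direction had not passed the threshold. Mcm3 (0.025) was -0.020 with DESeq2 size factors, -0.019 with the block, -0.019 with the DESeq2 Wald test, -0.23 with the length offset, -0.011 with limma on log2(TPM + 1), -0.011 with voom and -0.049 above the logCPM floor. Cd3d was 0.24 with the block, 0.33 with limma on log2(TPM + 1) and 0.17 with voom. With the length offset, Ebf2 was 0.021, Cpt1b 1.19, Mcm2 -0.039, Lck 0.22, Snhg11 0.69 and the brown and beige adipocyte median 0.54. With limma on log2(TPM + 1), Cygb was 0.038, Ebf2 0.18, Cpt1b 0.91, Lrp6 0.089, Lck 0.34, Snhg11 0.84, the brown and beige adipocyte median 0.67 and the complement median 0.49. Above the logCPM floor, Creb5 was -0.00059, mt-Co1 -0.0011 and the Dpp4-type median 0.025. For lists the direction is that of camera, which can differ from the median's sign.

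Leaving out each library in turn gave ranges of -0.23 to 0.49 for Col1a1, -0.074 to 0.62 for Col1a2, -0.55 to 0.20 for Sfrp2, -0.40 to 0.35 for Mcm3, -0.51 to 0.078 for Eng, -10.67 to 5.22 for Lck, -1.09 to 1.85 for Cd3d, -2.67 to 1.41 for Wt1 and -8.59 to 9.09 for Acta1. They were -0.025 to 0.16 for Creb5, -0.63 to 0.37 for Ebf2, -1.15 to 8.95 for Cxcr2, -0.11 to 0.24 for mt-Co1, -1.01 to 0.17 for Snhg11 and -10.29 to 0.89 for Atp2a1. Medians ranged from -0.13 to 0.30 for fibrillar collagens, -0.78 to 0.61 for brown and beige adipocyte, -0.082 to 0.40 for cytokines, -0.027 to 0.42 for p53 and senescence, -0.21 to 0.052 for Dpp4-type, -0.44 to -0.00052 for F3-type, 0.10 to 0.23 for basement membrane, 0.017 to 0.34 for complement, -0.14 to 0.28 for mature adipocyte, 0.049 to 0.30 for matrix protease and -0.088 to 1.13 for cell cycle genes. Low genes were measured least precisely: under an average logCPM of 2, replicates differed by a median of 3.34 on the log2 scale in the Mmp3-negative and 1.78 in the Mmp3-positive pair.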

Other observations

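Matrix proteases and inhibitors other than Mmp3 went both ways. Over 24 members the median log2 fold change was 0.17 (camera adjusted p = 0.468), with 0 past the threshold among all genes and 2 higher and 2 lower when adjusted over the list alone. Adamts1, a secreted metalloproteinase, stood at 1405 ± 121 CPM in Mmp3-negative and 1495 ± 93.1 CPM in Mmp3-positive libraries. Mmp19 and the metalloproteinase inhibitor Timp1 had log2 fold changes of 1.47 and 0.80, and the aggrecanases Adamts9 and Adamts4 had -1.62 and -2.77. Fibrillar collagens and matrix (median 0.10, Col1a2 4871 ± 1617 against 5731 ± 1472 CPM), basement membrane (0.19, with Hspg2, perlecan, at 3480 ± 465 against 4299 ± 27.5 CPM), complement (0.25, C3 at 1895 ± 12.2 against 2036 ± 11.5 CPM) and cytokine genes (0.02, Csf1 at 4813 ± 318 against 6440 ± 86.4 CPM) had camera adjusted p of 0.468, 0.240, 0.455 and 0.576. In these 4 lists the mean was negative while the median was positive and camera pointed up. With each library left out in turn the basement membrane median ran from 0.10 to 0.23 and the complement median from 0.017 to 0.34. The chemokines Ccl7 and Ccl11 had log2 fold changes of 1.05 and 1.21.

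Among progenitor and adipocyte lists, the Dpp4-type interstitial progenitor median was 0.01 and the F3-type regulatory stromal cell median 0.00, with camera pointing down (adjusted p = 0.368 and 0.468). With each library left out in turn these medians ran from -0.21 to 0.052 and from -0.44 to -0.00052. Mature adipocyte and brown and beige adipocyte medians were 0.00 and -0.04 (adjusted p = 0.370 and 0.584), with the lipase Pnpla2 at -2.25 and Plin4 at -1.01. The medians were 0.20 for TGF-beta and BMP signalling, 0.58 for retinoid metabolism, 0.06 for cell cycle, 0.16 for p53 and senescence and 0.23 for mitochondrially encoded genes (adjusted p = 0.373, 0.264, 0.240, 0.576 and 0.0822). With each library left out in turn the TGF-beta and BMP signalling median ran from -0.024 to 0.27 and that of retinoid metabolism from 0.13 to 0.79. Cyp26b1, which breaks down retinoic acid, had a log2 fold change of 1.03 and the p53 regulator Mdm2 0.71. The lists with under 5 tested members had medians of -0.24 (T and NK cell), -0.48 (B cell), -1.23 (skeletal muscle) and -1.24 (erythrocyte). With 1 tested member each, granulocyte and mast cell stood at 3.20 and nuclear long noncoding RNA at -0.30. The granulocyte member, Cxcr2, stood at 6.32 and 0.153 CPM in Mmp3-positive replicates 1 and 2. In the Mmp3-negative replicates it stood at 0 and 0.692 CPM. With genes at 0 in a group set to their bound, the mesothelial median was -2.80 and the mammary epithelium value -3.85.

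The tests of an alike lower share of other cell types, with and without each library, and of stress transcripts brought by them were chosen after the result was seen. The Mmp3-negative libraries had fewer genes with at least 10 counts. With all libraries thinned to the smallest total, the lowest Mmp3-positive library still had 719 more such genes than the highest Mmp3-negative one, against a range of 244 within the Mmp3-negative pair, which argues against depth. Without the 50 most abundant genes of each library the difference was 706, against a range of 243, which argues against a few genes taking the counts. The Mmp3-positive pair itself differed nearly as much as the groups. Its replicates 1 and 2 had 14329 and 13660 such genes after thinning, and 14243 and 13596 without the 50 most abundant. The size of the group difference is therefore uncertain. Of 12418 genes with at least 10 counts in both Mmp3-positive libraries, 646 were under 10 counts in both Mmp3-negative libraries. Of 10894 genes with at least 10 counts in both Mmp3-negative libraries, 221 were under 10 counts in both Mmp3-positive libraries. The 646 genes were 1.33 times the 487 that independent random loss gave at matched expression (highest of 1000 draws 531). The overlap was above every draw, which argues against independent loss at matched expression as the only source of these genes. The ratio lay between the bounds set for each explanation, so random loss in part and a smaller set of expressed genes cannot be told apart.

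The median log2 fold changes of mural, endothelial, macrophage and dendritic genes were between -2.90 and -1.80. With the list itself counted, at most 0.0073 of 10000 random lists matched on expression had a median as low. This argues against noise that is independent between genes. Genes were drawn singly, so noise shared by the markers of a cell type is not covered. With an estimated correlation the 4 lists did not pass (camera adjusted p between 0.192 and 0.389). The estimate was above the preset 0.01 for endothelial genes (0.244). It was under the preset for mural (-0.050), macrophage (-0.033) and dendritic genes (-0.032), so a higher correlation was not what ended those calls. The range of the 4 medians, 1.10, was no wider than in lists with shuffled genes (permutation p = 0.751), which is consistent with a lower share of all these cell types alike in the Mmp3-positive group, as a hypothesis. With a library left out in turn the range ran from 0.88 to 6.62 (permutation p between 0.0915 and 0.894), widest without Mmp3-positive replicate 1, where the dendritic median was -8.30. The size of that median, and so of that range, is uncertain, since H2-Eb1 had 0 counts in the remaining Mmp3-positive library. A p that misses the threshold does not show that the shares were equal, and a change within those cells stays open.

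The lower immediate early and heat shock genes were not set by reads shared between Hspa1a and Hspa1b alone: without the pair the list had a median of -0.62 over 20 members, of which 10 were lower when adjusted over the list alone. Its camera adjusted p was 2.94e-13 at the preset correlation and 0.264 with an estimated correlation, where the call of the full list was lost too (0.192). The estimated correlation and the count of members without the pair were added after the result was seen. With the list itself counted, 1e-04 of random lists had a median as low as -0.89, the smallest share that 10000 draws give. This argues against noise that is independent between genes, and noise shared by the members is not covered. Few members were low transcripts, since 21 of 22 had an average logCPM of at least 5. In 16 of 22 members the value was lower in both numbered sets. Whether other cell types brought these transcripts to the Mmp3-negative group cannot be told apart from a difference within stromal cells, since the median of -0.887 was above those of the mural, endothelial, macrophage and dendritic lists. A difference in handling between the groups was not tested.

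In both libraries of the Mmp3-negative group 424 tested genes were at 0 counts, and in both of the Mmp3-positive group 147. Against a floor of 3 counts per library, Meox2, a homeobox factor, was at least 88.8-fold higher in the Mmp3-positive libraries (6.42 and 23.3 CPM). Laptm5, a lysosomal protein of blood cells, was at least 229-fold lower there (17.69 and 53.45 CPM in the Mmp3-negative libraries). Neither passed the threshold (edgeR adjusted p = 0.480 for both). These folds, and those of Lmod1 and H2-Eb1, use the mean of the expressing group, so spread between replicates is not covered. Genes called in the same direction above the logCPM floor, by voom, by DESeq2 and with no filter numbered 18. Of these, 2 were higher and 16 lower. Among settings that kept all 4 libraries, these called the most genes, so the overlap does not measure robustness. The length offset called 1 gene and limma on log2(TPM + 1) 0. Apart from Mmp3, Hspa1a and Hspa1b, the 18 genes did not pass in the main test. They included Lama5, a laminin chain, at 203 ± 12.8 against 10.6 ± 6.98 CPM. A transcript of Ccnb1ip1, 444 bases long, held between 1.06% and 1.14% of the counts in each library and shared 203 of its 31-base words with Rpph1, the RNA of RNase P, which the tables do not list. The Y-linked genes Ddx3y, Kdm5d, Uty and Eif2s3y were detected in all 4 libraries, with Ddx3y between 12.4 and 39.1 CPM, and Xist was not analysed here.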
